A study of Mus musculus with 34 samples.

How the data were processed

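The series holds 34 one-color Agilent mouse arrays, each hybridized with Cy3-labelled cRNA from the liver of one male C57Bl/6J mouse. The series text speaks of 36 samples, but its group sizes and the deposited arrays both add up to 34. The samples were grouped by the genotype and treatment per the labels into 8 groups of 3 to 5 mice.

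The deposited scanner files hold spot intensities made by Agilent Feature Extraction 10.10.1.1 per the file headers, on a linear scale. The headers place the probes on the mm9 (NCBI37) mouse build. The authors' value table is in log2 units and is quantile normalized, and the median of every one of its columns was 7.63. The submitters' processing notes also name limma. For the 31 arrays of slides 2 to 5, the authors' log2 values tracked the log2 median spot intensity, taken without background correction or quantile normalization. The correlation across probes was at least 0.99955. For the 3 arrays of slide 1 this correlation was about 0.993, and the sources used here do not give the reason.

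The values analysed were the background-corrected processed intensities of the scanner files. Control spots were left out, leaving 59305 spots of 55681 probes. Spots marked as non-uniform or population outliers by the scanner software were set to missing, which left 84 missing values among the genes tested. Spots of the same probe were averaged, the values were taken to log2, and the 75th percentile of each array was subtracted. Levels below are therefore log2 intensities relative to the 75th percentile of the array.

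A gene name was found for 32480 probes, of which 27235 were named by accession, 3381 by symbol and 499 by synonym, and 1365 kept the name in the file. The other 23201 probes had none. The reference table of gene names belongs to a later build and was used for names alone. A probe entered when it was well above background on every array of at least 1 group, which 31058 probes did, 21200 of them named. Each gene was represented by its brightest probe, giving 15799 genes. Probes well above background made up 50.6% to 63.2% of each array (median 55.9%). The number of arrays limits the precision.

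Group means were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances from all 8 groups and no covariate. Every p for a gene is a two-sided limma p, adjusted by Benjamini-Hochberg over the 15799 genes of a comparison, with a threshold of 0.05. Errors of log2 changes are standard errors (SE), and errors of group levels are standard deviations (SD). The 12 comparisons were 7 between 2 groups and 5 differences between such effects (interaction tests). Where every array of 1 group was below background, the change is given as "at least N-fold", in place of the fitted change. It sets the mean of the bright group against the lowest value called well above background on each array of the dim group, or against the value of the array itself where that was higher. Where some arrays of a group were above background, their number is given, and where those limits lower the change it is given as "at least". Bounds are those of the brightest probe.

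Gene sets were 29 lists fixed before the data were examined, 9 of them markers of cell types. They were tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists of a comparison. For each list the number of called genes is also given when adjusted over the list alone. The named genes follow a rule fixed before the data were examined. It takes 12 anchor genes in each comparison of 2 groups, the 6 largest rises and 6 largest falls by fitted change among called genes with a proper gene name, and up to 4 called members of each list that was called or had at least 3 called members. From that set the text names a part, and 4 of its genes, 2 of them anchors, are not reported here. Of 158 pairs of a named gene's value and that of another detected probe of the gene, 4 had opposite signs, none of them with both probes called, and 41 second probes were not called.

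Slides, read from the layout of the arrays, were treated as batches. The changes of called genes were compared within slides that hold both groups, whose arrays also entered the calls, and every comparison was refitted with slide as a block. The replicate numbers were checked for pairing by correlating the deviations of same-numbered mice from their group means. The numbers were taken to pair the samples where every r was at least 0.1. This held in the 3 comparisons of vehicle groups (r from 0.119 to 0.289 for LKO and LWT, 0.122 to 0.403 for KO and WT, and 0.107 to 0.236 for WT and LWT). Many of these same-numbered mice also shared a slide, so pairing by number cannot be told apart from slide. By the same rule the numbers did not pair the samples for fenofibrate, where r ran from -0.109 to 0.089 in WT, -0.276 to 0.215 in LWT, -0.204 to 0.303 in LKO and -0.0890 to 0.114 in KO. The comparisons were fitted unpaired, and the fit with the replicate number as a block is among the alternatives.

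Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, median intensities without background correction, and the authors' values. They also included other filters on dim probes, keeping the outlier spots, averaging the probes of a gene, slide as a fixed or random block, the replicate block, a fit of the compared groups alone, an intensity trend in the variances, array weights, stricter thresholds, and leaving out each array in turn. Leaving out the 3 arrays of slide 1 was added after seeing the data. Chance was tested by refitting other splits of the same mice, up to 100 per comparison. Overlaps between lists of called genes were tested with Fisher's exact test (1-sided for a larger overlap) on comparisons that share no array, and positions on chromosomes with the 2-sided test. The fitting and the list tests were tested on simulated data with changes of known size. Tables were handled with jsonlite 2.0.0 and the data.table package, version 1.17.8, and figures drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.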

Results

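Gene expression was measured in the livers of 34 male mice of 14 weeks, killed at zeitgeber time 14 after 10 days of daily gavage. The drug was fenofibrate at 100 mg per kg per day, a fibrate that activates the nuclear receptor PPARA, and the vehicle was gum arabic at 3%. The mice were wild-type (WT, 4 vehicle and 4 fenofibrate), whole-body Ppara knockout (KO, 3 and 5), liver Ppara knockout (LKO, 4 and 5) and the control line of the liver knockout (LWT, 4 and 5). Probes well above background numbered 28188 to 35167 per array. Their share was similar across groups, from a mean of 54.8% in fenofibrate LWT to 59.2% in fenofibrate WT, and no spot was saturated. Replicates of a group correlated across probes at 0.979 to 0.995. Fold changes below are log2 ± SE from limma unless a ratio is named, and the n are those of the groups above.

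Ppara itself was lower in both knockouts. Its brightest probe (chromosome 15, 85632110 to 85632169 on mm9) read 6.84 ± 0.25 (SD, n = 4) in LWT vehicle mice and 5.94 ± 0.10 (n = 4) in LKO, a change of -0.91 ± 0.16 (adjusted p = 0.000262). In KO mice it read 5.14 ± 0.26 (n = 3) against 6.84 ± 0.19 (n = 4) in WT, a change of -1.70 ± 0.17 (adjusted p = 1.05e-08). The 3 probes of the gene gave 53.4%, 47.6% and 55.4% of the LWT level in LKO, and 30.7%, 22.2% and 32.7% of the WT level in KO. All 3 stayed above background in every group. The deleted part of the gene is not given in the sources used here, so a probe outside it would check nothing about the loss of a working transcript. Fenofibrate left Ppara without a call in WT (0.03 ± 0.16, adjusted p = 0.930), LWT (-0.01 ± 0.15, adjusted p = 0.981), LKO (-0.10 ± 0.15, adjusted p = 0.994) and KO (0.29 ± 0.16, adjusted p = 0.498).

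**Figure D1:**
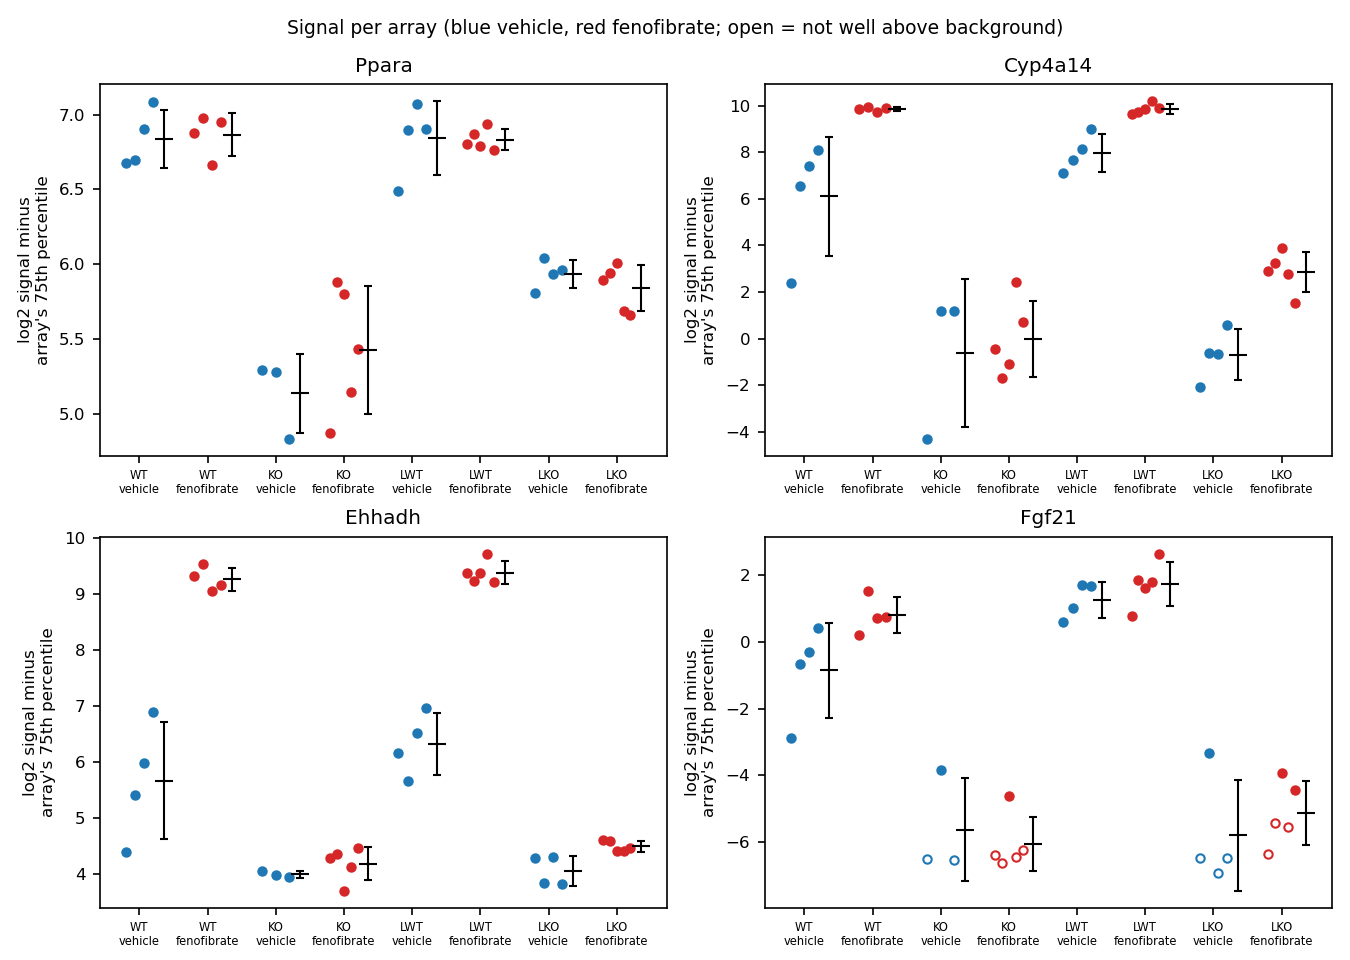
Log2 level of Ppara, Cyp4a14, Ehhadh and Fgf21 relative to the 75th percentile of the array, 1 point per mouse in each of the 8 groups, with open points for arrays not well above background and black bars for the mean ± SD. Ehhadh averaged 5.67 in WT vehicle mice and 9.26 in WT fenofibrate mice, and 4.00 and 4.19 in the KO groups.

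The first question was what fenofibrate changed in WT liver. Genes of fatty acid uptake and oxidation rose strongly. Acot2, a mitochondrial acyl-CoA thioesterase, rose 44.5-fold (5.48 ± 0.38), Pdk4, a kinase that restrains pyruvate oxidation, 25.1-fold (4.65 ± 0.50), and Cd36, a fatty acid translocase, 12.1-fold (3.60 ± 0.19, adjusted p = 3.60e-14). Ehhadh, the peroxisomal bifunctional enzyme, also rose 12.1-fold (3.59 ± 0.30). For these 4 genes every treated mouse lay above every vehicle mouse. In all, 1614 genes rose and 1783 fell of 15799 tested, and among changes of at least 2-fold 417 rose and 273 fell.

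Of 28 measured genes of peroxisomal fatty acid oxidation, 24 rose and 0 fell (24 also when adjusted over the list alone), among them Acot5 (3.97 ± 0.67) and Acot6 (2.68 ± 0.26, but 0.65 with adjusted p = 0.0804 at a second probe). All 22 genes of mitochondrial fatty acid oxidation rose (22 adjusted over the list alone), including the carnitine genes Cpt1b (2.04 ± 0.20), Slc22a5 (1.68 ± 0.24) and Slc25a20 (1.15 ± 0.13). Of 13 genes of microsomal omega-oxidation 10 rose and 1 fell (10 and 1 adjusted over the list alone). They include Cyp4a10 (2.52 ± 0.67, adjusted p = 0.00679) and Cyp4a14 (3.75 ± 1.02, adjusted p = 0.00800, but 0.0618 without replicate 1 of the WT vehicle group). Other PPARA target genes gave 17 up and 1 down of 19, with Vnn1 up 3.07 ± 0.40 and Fbp2 at least 4.09-fold higher. Lipid uptake and droplet genes gave 18 up and 1 down of 27 (21 and 2 adjusted over the list alone). Examples are Cidec (4.17 ± 0.61), Lpl (3.11 ± 0.36) and the droplet coat gene Plin2 (2.03 ± 0.26). The camera adjusted p of these 5 lists were 9.88e-24, 6.79e-24, 1.37e-06, 2.50e-13 and 2.78e-12. With an estimated correlation they stayed called, at 0.00235, 0.00369, 0.00369, 0.00102 and 0.00102.

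Other lipid genes moved too. Of 6 ketogenesis genes 2 rose, Acat1 (0.84 ± 0.11) among them (list adjusted p = 0.00674, adjusted p = 0.0848 with an estimated correlation). Fatty acid and triglyceride synthesis had 7 up and 4 down of 24 (9 and 4 adjusted over the list alone). Mogat1, a monoacylglycerol acyltransferase, rose 29.8-fold (4.90 ± 0.26) and Acacb rose 1.39 ± 0.17 (list adjusted p = 0.00909, adjusted p = 0.389 with an estimated correlation). Cholesterol synthesis had 10 up and 1 down of 25, led by Hmgcs1 (1.60 ± 0.35) and Hsd17b7 (1.17 ± 0.21, but 0.58 with adjusted p = 0.0552 at 1 of 2 other probes), with a list adjusted p of 0.00175 (adjusted p = 0.595 with an estimated correlation). Other large rises included Rad51b (6.07 ± 0.53), Krt23 (5.14 ± 0.33) and Ctse, at least 11.2-fold higher. Large falls included Sdr9c7 (-2.78 ± 0.26), Adgrf1 (-2.43 ± 0.37) and Ces1a, at least 3.21-fold lower.

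Further lists were called in WT with the preset correlation alone. Gluconeogenesis and glucose handling had 7 down and 2 up of 17, with Tkfc (-0.90 ± 0.19) and Khk (-0.62 ± 0.14) lower (list adjusted p = 0.0164, adjusted p = 0.170 with an estimated correlation). Amino acid catabolism and the urea cycle had 12 down and 2 up of 30 (12 and 4 adjusted over the list alone), with Gls2 at -0.78 ± 0.13 (list adjusted p = 0.0257, adjusted p = 0.595 with an estimated correlation). Without replicate 4 of the WT vehicle group this list had an adjusted p of 0.0793, and without replicate 3 of the WT fenofibrate group 0.0607. Of 18 circadian clock genes 6 fell, including Usp2 (-0.75 ± 0.16) and Per1 (-0.56 ± 0.11, but -0.04 with adjusted p = 0.931 at a second probe) (list adjusted p = 0.0112, adjusted p = 0.109 with an estimated correlation). Of 15 hepatocyte marker genes 4 fell, among them Cps1 (-0.44 ± 0.11) and Trf (-0.40 ± 0.09, but -0.13 with adjusted p = 0.566 at a second probe) (list adjusted p = 0.00909, adjusted p = 0.389 with an estimated correlation). The female-biased liver genes had 5 up and 0 down of 14, with Slc22a27 at least 2.65-fold higher (list adjusted p = 0.0197, adjusted p = 0.231 with an estimated correlation). Cholangiocyte markers were called up with 1 of 11 genes past the test, Krt23 (list adjusted p = 0.0161, adjusted p = 0.231 with an estimated correlation).

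The remaining lists in WT had no call. Bile acid synthesis and transport had 4 up and 4 down of 21, including Slco1a4 (-1.88 ± 0.24) and Abcc3 (0.94 ± 0.13). Apolipoproteins and lipoprotein metabolism had 2 up and 3 down of 19, with Pltp up 2.41 ± 0.26, and hepatokines had 3 up and 7 down of 20, with Igfals at -1.0 ± 0.21. Xenobiotic metabolism had 5 up and 5 down of 30, including Cyp2b10 (3.27 ± 0.83), and the median (-0.13) and mean (0.03) of that list differed in sign. The hepatokine list too had a median of -0.11 beside a mean of 0.05. The acute phase response had 1 up and 7 down of 27, oxidative and ER stress 2 up and 5 down of 22, and male-biased genes 2 up and 6 down of 17. The cell cycle list had 0 up and 4 down of 24 beside a median of 0.25. Among markers, 1 of 15 Kupffer cell genes (0 adjusted over the list alone) and 1 of 14 lymphocyte and neutrophil genes rose. No gene of 13 stellate cell or 13 endothelial genes passed limma's test. Of adipocyte markers 1 rose and 1 fell of 5, and 1 fell of 4 pancreatic acinar (median 0.06, mean -0.26) and of 7 red blood cell markers.

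With slide as a block 3191 genes were called in WT, and on slide 3, the 1 slide with both groups, 99.7% of the 3397 called genes moved the same way (2 treated mice against 1). These arrays also entered the calls, as in the later comparisons, so shares within slides are no separate test of slides.

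**Figure D2:**
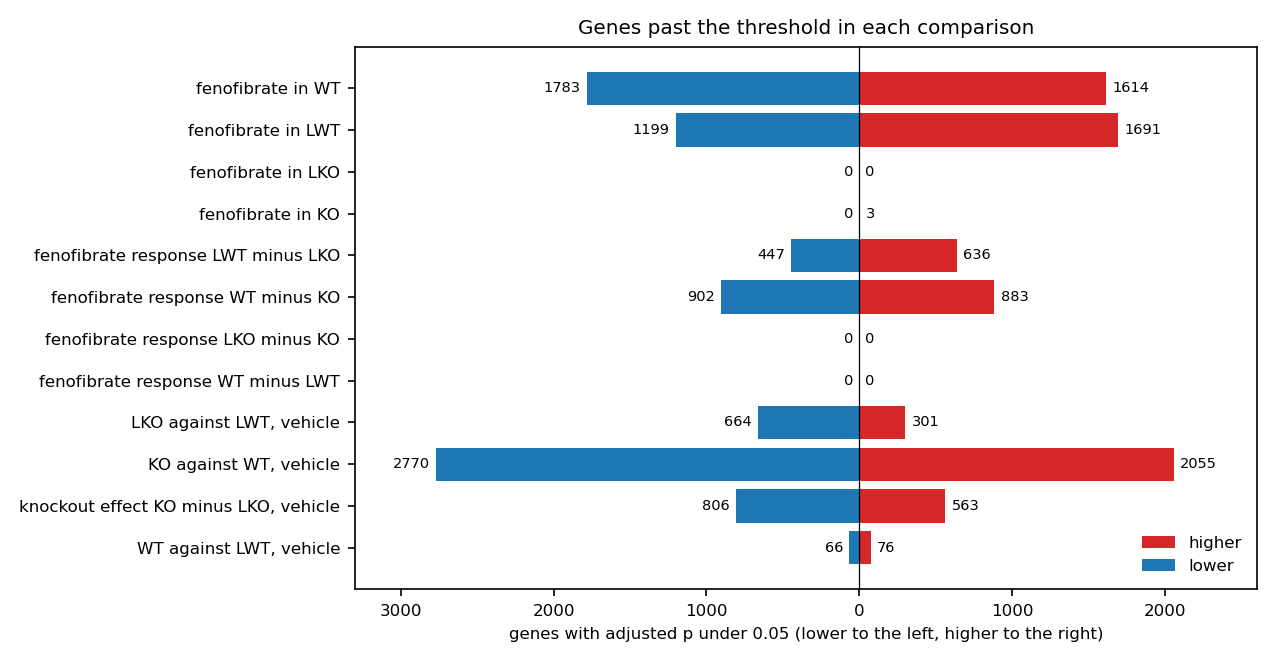
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons, higher as bars to 1 side and lower as bars to the other. Fenofibrate changed 3397 genes in WT and 2890 in LWT, 0 in LKO and 3 in KO.

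The same question in LWT mice gave a like answer. Cd36 rose 14.7-fold (3.87 ± 0.18), Acot2 26.5-fold (4.73 ± 0.36), Mogat1 23.3-fold (4.54 ± 0.25) and Vldlr, a lipoprotein receptor, 20.3-fold (4.35 ± 0.41). Ehhadh (3.06 ± 0.29), Pdk4 (3.75 ± 0.48), Vnn1 (2.74 ± 0.38) and Plin2 (1.13 ± 0.25) rose as well. Cyp4a10 (1.02 ± 0.63, adjusted p = 0.293), Cyp4a14 (1.90 ± 0.97, adjusted p = 0.188), Cpt1a (0.11 ± 0.08) and Fgf21 (0.50 ± 0.68) were not called. For Cyp4a10 and Cyp4a14 every treated LWT mouse still lay above every LWT vehicle mouse. The lowest treated mouse read 9.66 for Cyp4a14 and the highest vehicle mouse 9.01, and for Cyp4a10 they read 9.70 and 9.27. Their SE draw on the spread within all 8 groups, so the missing calls do not show a missing response. In WT, Cpt1a had passed at 0.26 ± 0.08 (adjusted p = 0.105 without replicate 1 of the WT vehicle group, and 0.26 with adjusted p = 0.148 at a second probe) and Fgf21 had not (1.65 ± 0.72, adjusted p = 0.101). In LWT 1691 genes rose and 1199 fell, and 298 and 245 did so at least 2-fold.

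Peroxisomal oxidation genes gave 23 up and 0 down of 28 in LWT (24 adjusted over the list alone), mitochondrial oxidation 19 up of 22 (21), omega-oxidation 6 up and 1 down of 13, other PPARA targets 11 up and 1 down of 19, and lipid uptake and droplets 16 up and 2 down of 27. Among them were Aldh3a2 (2.17 ± 0.14), Cyp4f18 (1.96 ± 0.10), Acadm (1.06 ± 0.12) and Lpl (3.48 ± 0.35). These 5 lists were called with the preset correlation (adjusted p = 8.30e-21, 1.39e-20, 0.000112, 5.93e-09 and 3.21e-08) and with an estimated correlation (adjusted p = 0.00674, 0.00954, 0.0205, 0.00674 and 0.00733). Circadian clock genes had 5 down of 18, including Usp2 (-0.93 ± 0.15) and Nfil3 (-0.94 ± 0.20), and this list too was called both ways (adjusted p = 0.00219, adjusted p = 0.0432 with an estimated correlation). Male-biased genes had 7 down and 2 up of 17, including Hsd3b5 (-2.15 ± 0.53) (list adjusted p = 0.00173, adjusted p = 0.233 with an estimated correlation). Acute phase genes had 5 down and 2 up of 27, including Saa4 (-0.96 ± 0.21), while Il1rn rose 3.03 ± 0.27 (list adjusted p = 0.0302, adjusted p = 0.633 with an estimated correlation).

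Further lists called in LWT with the preset correlation were ketogenesis, 2 up of 6 (adjusted p = 0.0433, adjusted p = 0.233 with an estimated correlation), and fatty acid and triglyceride synthesis, 8 up and 1 down of 24 (adjusted p = 0.0149, adjusted p = 0.393 with an estimated correlation). Gluconeogenesis had 3 down of 17, Khk among them at -0.48 ± 0.13 (adjusted p = 0.0397, adjusted p = 0.233 with an estimated correlation), and 3 of 15 hepatocyte markers fell (adjusted p = 0.00303, adjusted p = 0.344 with an estimated correlation). Leaving out 1 array ended 4 of these calls, with the highest adjusted p for the acute phase list 0.0875 without replicate 2 of LWT vehicle. For fatty acid synthesis it was 0.0559 without that same mouse, for gluconeogenesis 0.0931 without replicate 1 of LWT vehicle, and for ketogenesis 0.0686 without replicate 2 of LWT fenofibrate. Cholangiocyte markers had a median of -0.41 and a mean of 0.07, with no call. Large changes included Adra2a (at least 19.8-fold higher), Smcp (at least 42.3-fold), Rad51b (6.11 ± 0.50), Serpina12 (at least 4.02-fold lower) and Adgrf1 (-2.72 ± 0.35). A slide block gave 2844 genes, and 99.4% and 99.5% of called genes moved the same way within slides 2 and 3.

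The WT and LWT responses, which share no mice, overlapped. Of the genes raised, 1104 were shared against 172.7 expected by chance, and of those lowered 869 against 135.3. No gene was called in opposite directions, where 122.5 and 190.8 were expected. Across all genes, which are not independent replicates, the changes correlated at r = 0.811 (rho = 0.695), and 98.2% of genes called in WT had the same sign in LWT. The difference between the responses (WT minus LWT) was called by limma for 0 genes, with 696 at an unadjusted p under 0.05, and for 2 genes without replicate 3 of LWT fenofibrate or 1 without replicate 3 of WT fenofibrate. Lists were called even so. Peroxisomal oxidation (median 0.21), mitochondrial oxidation (0.18), other PPARA targets (0.27), lipid uptake (0.23), cholesterol synthesis (0.29) and cholangiocyte markers (0.95) leaned to a larger rise in WT, with 0 members called in each. Their adjusted p of 0.000713, 0.000106, 0.000186, 0.000587, 0.000134 and 1.43e-05 became adjusted p = 0.629, 0.605, 0.164, 0.174, 0.747 and 0.0725 with an estimated correlation. The peroxisomal list had an adjusted p of 0.0925 without replicate 1 of WT vehicle. Mean levels in treated WT and LWT mice were 5.86 and 5.99 for peroxisomal oxidation, 6.39 and 6.47 for mitochondrial oxidation and 4.03 and 4.04 for other PPARA targets. With vehicle they were 4.57 and 4.81, 5.31 and 5.60, and 2.52 and 2.86. The larger rise of these lists in WT thus began from a lower vehicle level and did not end higher. The other lists named here ended higher in treated WT mice.

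**Figure D3:**
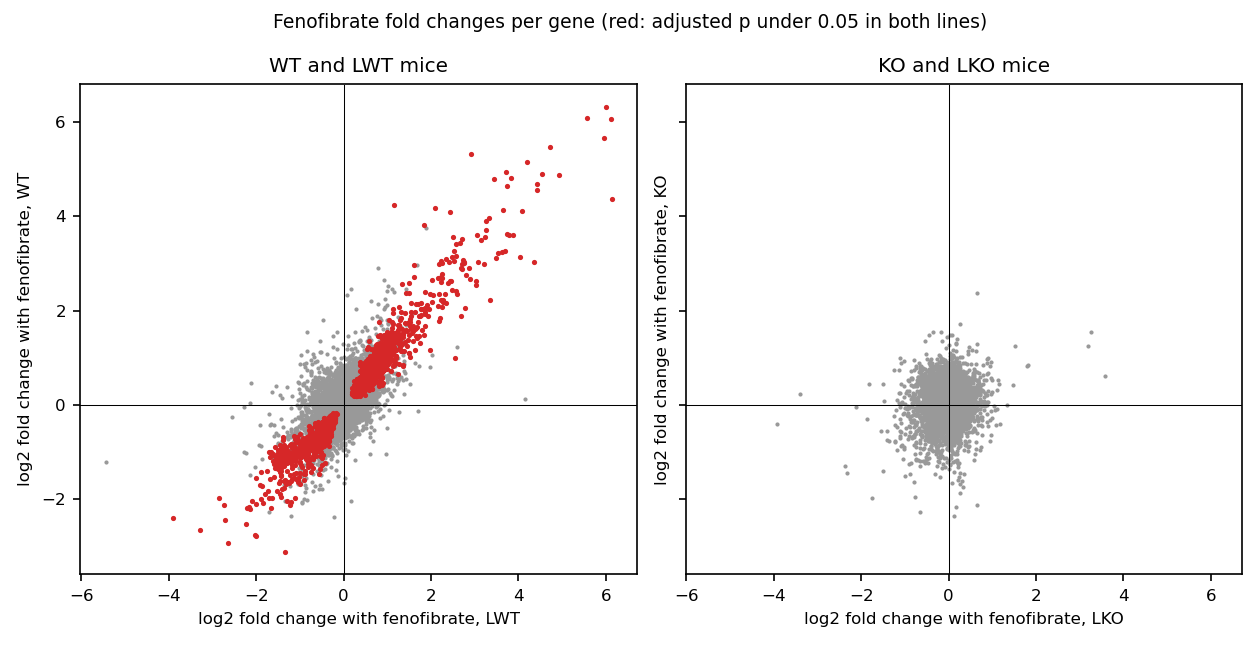
Log2 change with fenofibrate for every gene, LWT against WT in the left panel and LKO against KO in the right panel. The changes in WT and LWT lie along a line (r = 0.811 across genes), and those in KO and LKO do not (r = 0.055).

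The next question was whether the response needed PPARA in the liver. In LKO mice limma called 0 genes for fenofibrate, with 904 at an unadjusted p under 0.05. Cd36 read -0.07 ± 0.18, Ehhadh 0.44 ± 0.29, Pdk4 0.36 ± 0.48, Plin2 -0.31 ± 0.25 and Cpt1a -0.18 ± 0.08. Cyp4a14 (3.57 ± 0.97, adjusted p = 0.447) and Cyp4a10 (1.81 ± 0.63, adjusted p = 0.698) had large changes that were not called. In both genes every treated mouse lay above every vehicle mouse. Cyp4a14 read 1.5 to 3.9 in treated and -2.1 to 0.6 in vehicle mice, and Cyp4a10 3.2 to 4.7 and 1.7 to 2.6. The SE of both draws on the spread within all 8 groups. Vnn1 (0.52 ± 0.38) was above background on 3 of 4 vehicle and 5 of 5 treated arrays, and Fgf21 (0.66 ± 0.68) on 1 of 4 and 2 of 5. When adjusted over the list alone, 4 omega-oxidation genes passed.

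Some lists were called in LKO with no gene past the test. Omega-oxidation (median 0.14, adjusted p = 0.00115, adjusted p = 0.185 with an estimated correlation), xenobiotic metabolism (0.20, adjusted p = 0.000173 and adjusted p = 0.364 with an estimated correlation) and endothelial markers (0.18, adjusted p = 0.000221 and adjusted p = 0.185 with an estimated correlation) leaned up. The acute phase response (median -0.34, adjusted p = 3.15e-10, adjusted p = 0.364 with an estimated correlation), male-biased genes (-0.10, 0.0348 and adjusted p = 0.687 with an estimated correlation) and cholesterol synthesis (-0.14, 0.0390 and adjusted p = 0.893 with an estimated correlation) leaned down. So did apolipoproteins (-0.09, 0.0390 and adjusted p = 0.687 with an estimated correlation) and hepatocyte markers (-0.07, 0.0490 and adjusted p = 0.883 with an estimated correlation). For the last 4 lists leaving out 1 array could end the call, at the most adjusted p = 0.112, 0.376, 0.220 and 0.375, the first without replicate 3 of LKO vehicle, the second without replicate 5 and the others without replicate 4 of LKO fenofibrate. The gene count was 3 without replicate 3 or 5 of LKO fenofibrate or replicate 1 of KO vehicle, 2 without replicate 5 of LWT fenofibrate and 1 without replicate 2 of WT fenofibrate.

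Tested as a difference of signed log2 changes, LWT minus LKO was positive for 636 genes and negative for 447. Of the 447, 380 were among the 869 genes lowered in both control lines, which fell more in LWT than in LKO. The difference was 3.95 ± 0.25 for Cd36 (adjusted p = 9.64e-12), 4.63 ± 0.51 for Acot2, 2.62 ± 0.40 for Ehhadh, 3.39 ± 0.67 for Pdk4 and 4.77 ± 0.35 for Mogat1. Of 28 peroxisomal oxidation genes 16 differed (20 adjusted over the list alone), of 22 mitochondrial ones 15 (21), of 19 other PPARA targets 9 up and 1 down, of 27 lipid uptake genes 8 up and 1 down, all with list calls (adjusted p = 7.97e-19, 7.97e-19, 3.55e-07 and 9.58e-08) that held with an estimated correlation (adjusted p = 0.0138, 0.0140, 0.0140 and 0.0138). Examples are Cpt1b (1.70 ± 0.27), Slc27a1 (2.02 ± 0.27) and Lpl (3.50 ± 0.49). Circadian clock genes differed downward for 2 of 18, Usp2 (-1.03 ± 0.22) and Per1 (-0.64 ± 0.15, and -0.60 with adjusted p = 0.315 at a second probe) (list adjusted p = 0.00246, adjusted p = 0.0463 with an estimated correlation). Omega-oxidation had 5 up and 1 down of 13, with Cyp4f18 at 1.91 ± 0.14 (adjusted p = 0.0252, adjusted p = 0.221 with an estimated correlation, and 0.0559 with the preset one without replicate 4 of LKO vehicle). Slco1a4 (-2.23 ± 0.32) and Gstp1 (-1.08 ± 0.20) differed downward. A block for slide gave 1400 genes.

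In KO mice fenofibrate raised 3 genes, Podxl (1.03 ± 0.19, adjusted p = 0.0415, above background on 2 of 3 vehicle arrays), Naaladl2 (0.84 ± 0.15, adjusted p = 0.0284, but 0.45 with adjusted p = 0.438 at a second probe) and Itm2b (0.58 ± 0.10, adjusted p = 0.0284), and lowered 0. The count at an unadjusted p under 0.05 was 1869. Cd36 read 0.10 ± 0.19, Ehhadh 0.19 ± 0.31, Pdk4 0.15 ± 0.52, Plin2 0.07 ± 0.27, Cyp4a10 0.85 ± 0.69, Cyp4a14 0.61 ± 1.05 and Cpt1a 0.21 ± 0.08, none called. Vnn1 was above background on 1 of 3 vehicle and 0 of 5 treated arrays, and Fgf21 on 1 of 3 and 1 of 5. The count rests on single mice. It was 81 without replicate 3 and 32 without replicate 2 of KO vehicle, 18, 0 and 1 without replicates 1, 2 and 5 of KO fenofibrate, and 5 without replicate 5 of LWT fenofibrate. The 3 calls were lost without replicate 1 of KO vehicle, with adjusted p of 0.0874, 0.0856 and 0.0839 in the order above. Fitted with a slide block the count was 24, 21 up and 3 down, and the 3 genes moved the same way within slides 1, 2 and 5.

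Lists called in KO with no member past the test leaned up for omega-oxidation (median 0.31), ketogenesis (0.30), other PPARA targets (0.09), bile acid synthesis and transport (0.26), hepatokines (0.14), xenobiotic metabolism (0.27), male-biased genes (0.45), endothelial markers (0.15) and red blood cell markers (0.75). They leaned down for cholesterol synthesis (-0.27), the acute phase response (-0.40) and Kupffer cell markers (-0.28). In this order the adjusted p were 0.0126, 0.00624, 0.0485, 0.000476, 0.00903, 0.000476, 0.00230, 0.00688, 0.000685, 0.00368, 1.95e-05 and 0.00688. They became adjusted p = 0.264, 0.244, 0.418, 0.244, 0.264, 0.264, 0.264, 0.264, 0.358, 0.615, 0.399 and 0.612 with an estimated correlation. Without replicate 1 of KO vehicle the omega-oxidation (0.496), PPARA target (0.376), hepatokine (0.0610, and 0.155 without replicate 3), cholesterol (0.804), acute phase (0.253) and endothelial (0.217) calls were lost. Without replicate 3 of KO vehicle the ketogenesis (0.36), male-biased (0.0846) and red blood cell (0.166) calls were lost, and without replicate 2 the Kupffer call (0.590).

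The signed difference, WT minus KO, was positive for 883 genes and negative for 902. Of the 902, 528 were among the 869 genes lowered in both control lines, which fell more in WT than in KO. Cd36 differed by 3.50 ± 0.27, Acot2 by 5.60 ± 0.54, Ehhadh by 3.40 ± 0.43, Pdk4 by 4.50 ± 0.72 and Krt23 by 4.77 ± 0.47. Peroxisomal oxidation differed for 20 of 28 genes (23 adjusted over the list alone), mitochondrial oxidation for 16 of 22 (18), other PPARA targets for 9 up and 1 down of 19, and lipid uptake for 14 up and 1 down of 27. These lists were called (adjusted p = 9.24e-19, 1.17e-17, 1.20e-08 and 9.69e-09) and kept the call with an estimated correlation (adjusted p = 0.00763, 0.0190, 0.00763 and 0.00763). Cholesterol synthesis had 8 up of 25, with Hmgcs1 at 2.37 ± 0.51 (adjusted p = 3.18e-05, adjusted p = 0.387 with an estimated correlation). Amino acid catabolism had 7 down of 30, Otc among them at -0.80 ± 0.14 (adjusted p = 0.00721, adjusted p = 0.424 with an estimated correlation). Bile acid genes had 4 down and 2 up of 21, with Slco1a1 at -1.83 ± 0.25 (adjusted p = 0.0188, adjusted p = 0.296 with an estimated correlation). The count with a slide block was 2162.

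The other lists called in WT minus KO were not called with an estimated correlation. Omega-oxidation had 3 up and 1 down of 13 (adjusted p = 0.00249, adjusted p = 0.0767 with an estimated correlation), with Cyp4f18 at 2.27 ± 0.15 and Cyp4f14 at -1.27 ± 0.18. Circadian genes had 3 down of 18, with Usp2 at -1.13 ± 0.23 (adjusted p = 0.00474, adjusted p = 0.0767 with an estimated correlation). Male-biased genes had 5 down of 17, with Hsd3b5 at -2.98 ± 0.81 (0.00249, and adjusted p = 0.211 with an estimated correlation), and hepatokines 4 down of 20, with Igfals at -1.23 ± 0.31 (0.0193, and adjusted p = 0.211 with an estimated correlation). Gluconeogenesis had 6 down of 17, with Tkfc at -1.07 ± 0.27, whose own adjusted p was 0.0503 without replicate 3 of KO vehicle (list adjusted p = 0.0167, and adjusted p = 0.188 with an estimated correlation), and xenobiotic metabolism 7 down and 2 up of 30, with Gstp1 at -1.21 ± 0.22 and Abcc4 at 1.62 ± 0.23 (0.0482, and adjusted p = 0.501 with an estimated correlation). Female-biased genes had 2 up of 14 (0.0482, and adjusted p = 0.319 with an estimated correlation). Of markers, cholangiocytes had 2 up of 11 (0.00703), hepatocytes 2 down of 15 (0.00761), red blood cells 1 down of 7, Alas2 at -1.07 ± 0.21 (0.0152), and Kupffer cells 0 of 15 (median 0.54, 0.0167). These became adjusted p = 0.188, 0.361, 0.438 and 0.524 with an estimated correlation. Leaving out 1 array ended the preset call of 6 of these lists. Without replicate 1 of KO vehicle hepatokines had 0.0581 and xenobiotic metabolism 0.221, without replicate 2 Kupffer cells 0.579, and without replicate 3 female-biased genes 0.120, gluconeogenesis 0.0515 and red blood cells 0.109.

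Among 1104 genes raised in both control lines the median change was 0.02 in LKO and -0.01 in KO, with 58.4% and 48.9% moving the same way, against medians of 0.60 in LWT and 0.66 in WT. Among 869 lowered genes the medians were -0.01 in LKO and 0.05 in KO. LKO and KO mice gave 0 genes for a difference between their responses, with 1460 at an unadjusted p under 0.05 by limma. That count was 13 without replicate 4 of LKO fenofibrate, 6 without replicate 1 of KO vehicle and 2 without replicate 1 of LKO vehicle. Male-biased genes (median -0.54, adjusted p = 0.000295), red blood cell markers (-0.66, 0.00854), amino acid catabolism (-0.16, 0.0438) and apolipoproteins (-0.15, 0.0469) were called lower in LKO minus KO. None was called with an estimated correlation (adjusted p = 0.596, 0.596, 0.801 and 0.596). Without replicate 3 of KO vehicle the red blood cell (0.297) and apolipoprotein (0.299) calls were lost, and without replicate 2 the amino acid call (0.363).

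**Figure D4:**
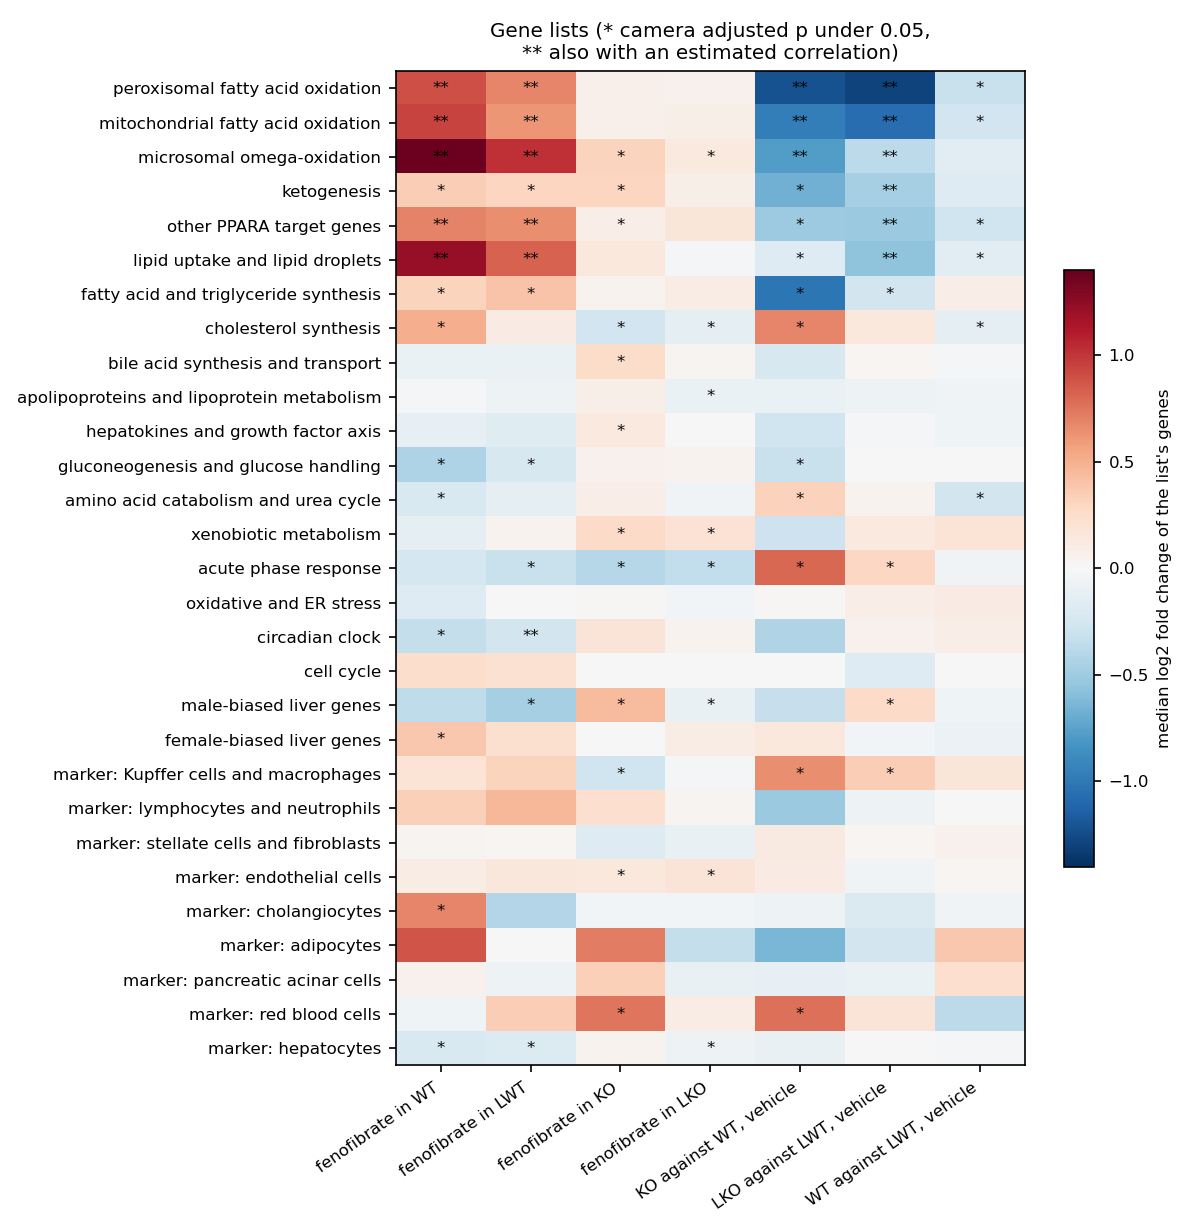
Median log2 change of each of the 29 gene lists (vertical axis) in each of the 7 comparisons between 2 groups (horizontal axis) as colors, with 1 star for lists called by camera and 2 stars for lists also called with an estimated correlation. Lists of fatty acid oxidation stand out as higher with fenofibrate in WT (median 0.95 for mitochondrial oxidation) and lower in LKO vehicle mice (median -1.07).

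Without the drug, the liver knockout showed which genes differed from the LWT controls in vehicle mice. Direct and indirect effects of losing hepatic PPARA were not separated. In LKO against LWT (4 and 4) Cyp4a14 fell by 8.68 ± 1.02 and Cyp4a10 by 6.83 ± 0.67 on the log2 scale, both omega-hydroxylases. Vnn1 fell by 6.17 ± 0.40 (3 of 4 LKO arrays above background) and the hepatokine gene Fgf21 by at least 5.64 (1 of 4). Ehhadh fell by 2.26 ± 0.30 and Plin2 by 1.33 ± 0.26. Cpt1a (-0.26 ± 0.08, adjusted p = 0.0529), Pdk4 (-1.50 ± 0.50, adjusted p = 0.0776) and Cd36 (-0.05 ± 0.19, adjusted p = 0.935) were not called. In all 301 genes were higher and 664 lower, with 96 and 225 at least 2-fold.

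Peroxisomal oxidation had 21 genes lower of 28 (22 adjusted over the list alone, with 1 higher), among them Decr2 (-2.46 ± 0.13) and Acaa1b (-2.35 ± 0.21), and mitochondrial oxidation 21 of 22 (22), among them Slc25a20 (-2.43 ± 0.13) and Etfdh (-1.94 ± 0.10). Omega-oxidation had 7 lower and 1 higher of 13, ketogenesis 3 lower of 6, other PPARA targets 10 lower of 19 (13 adjusted over the list alone), including Retsat (-2.52 ± 0.23) and Txnip (-1.79 ± 0.21), and lipid uptake and droplets 11 lower and 1 higher of 27, including Cidec (-3.81 ± 0.61) and Plin5 (-2.57 ± 0.48). These 6 lists were called (adjusted p = 7.76e-41, 1.05e-53, 5.97e-11, 0.000153, 2.56e-14 and 2.73e-11), and also with an estimated correlation (adjusted p = 9.89e-05, 9.45e-05, 0.000182, 0.0120, 0.000182 and 0.000700). Fatty acid synthesis had 5 lower of 24, with Gpam (-1.39 ± 0.21) and Fads2 (-1.19 ± 0.14) (adjusted p = 0.00523, adjusted p = 0.537 with an estimated correlation, and 0.0633 with the preset one without replicate 1 of LWT vehicle). Of other members, Igfbp2 (-1.44 ± 0.20), Abcb4 (-0.92 ± 0.11) and Angptl4 (-0.78 ± 0.10) were lower and Slco1a4 (1.13 ± 0.24) higher.

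Male-biased genes had 3 higher and 1 lower of 17 (adjusted p = 0.0371, adjusted p = 0.610 with an estimated correlation, and 0.178 with the preset one without replicate 4 of LWT vehicle). Acute phase genes (median 0.29, adjusted p = 0.000284) and Kupffer cell markers (median 0.35, adjusted p = 0.0307) were called higher with 0 members past the test, and not with an estimated correlation (adjusted p = 0.620 and 0.688). Without replicate 3 of LWT vehicle the Kupffer list had an adjusted p of 0.270. Bile acid genes had 1 higher and 4 lower of 21, with a median of 0.02 and a mean of -0.03, and were not called. Large rises included Tmeff2 (at least 9.13-fold), Serpinb1a (3.20 ± 0.44) and Gdpd3 (5.01 ± 0.89, above background on 2 of 4 LWT arrays). A slide block gave 1198 genes, and 99.5%, 99.9% and 100% of called genes moved the same way within slides 2, 3 and 4. With the replicate number as a block 1033 were called, and Pdk4 passed (adjusted p = 0.0361).

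The whole-body knockout gave a wider change in vehicle mice (3 KO and 4 WT). Cyp4a14 fell by 6.75 ± 1.1, Cyp4a10 by 5.35 ± 0.72 and Ehhadh by 1.67 ± 0.33. Vnn1 fell by at least 6.32 and Fgf21 by at least 3.42, each above background on 1 of 3 KO arrays. Cpt1a (-0.08 ± 0.09), Pdk4 (-0.34 ± 0.54), Cd36 (-0.19 ± 0.20) and Plin2 (-0.59 ± 0.29, adjusted p = 0.117) were not called. On the other side the acute phase genes Lcn2 (6.37 ± 0.89), Saa2 (4.81 ± 0.96) and Saa1 (4.61 ± 0.94) rose. In all 2055 genes were higher and 2770 lower, and 545 and 644 did so at least 2-fold. The share of called genes that were higher, 42.6%, depended on the scaling and was 51.1% after quantile normalization, 52.3% with quantile-normalized median signals and 52.7% with the authors' values.

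Peroxisomal oxidation had 22 lower and 1 higher of 28, with Ech1 (-2.48 ± 0.12) and Acot3 (-4.30 ± 0.56) lower and Acot6 higher (2.45 ± 0.28). Mitochondrial oxidation had 19 lower of 22, with Slc25a20 (-2.35 ± 0.14) and Cpt2 (-1.63 ± 0.16), and omega-oxidation 9 lower of 13 (11 adjusted over the list alone, with 1 higher). These 3 lists were called (adjusted p = 1.45e-13, 3.67e-16 and 0.000157), and with an estimated correlation each had adjusted p = 0.0424. Fatty acid and triglyceride synthesis had 18 lower and 1 higher of 24, with Srebf1, a regulator of lipogenesis (-2.26 ± 0.33), Elovl6 (-2.26 ± 0.42) and Gpam (-1.77 ± 0.22) (adjusted p = 2.51e-05, adjusted p = 0.180 with an estimated correlation). Other PPARA targets had 11 lower and 2 higher of 19 (adjusted p = 0.000976, adjusted p = 0.180 with an estimated correlation), and ketogenesis 4 lower and 1 higher of 6 (adjusted p = 0.0264, adjusted p = 0.20 with an estimated correlation). Lipid uptake and droplets had 9 lower and 2 higher of 27, including G0s2 (-3.19 ± 0.32) (adjusted p = 0.0281, adjusted p = 0.299 with an estimated correlation, and 0.140 with the preset one without replicate 1 of KO vehicle). Gluconeogenesis had 7 lower of 17, with Gys2 at -1.47 ± 0.18 (adjusted p = 0.0363, adjusted p = 0.253 with an estimated correlation, and 0.0927 with the preset one without replicate 3 of KO vehicle).

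Acute phase genes had 18 higher of 27 (23 adjusted over the list alone, adjusted p = 1.68e-10, adjusted p = 0.197 with an estimated correlation). Amino acid catabolism had 14 higher and 1 lower of 30, with Asns (2.82 ± 0.69) and Cth (1.19 ± 0.20) (adjusted p = 6.21e-05, adjusted p = 0.253 with an estimated correlation). Cholesterol synthesis had 13 higher and 1 lower of 25, with Sqle at 2.35 ± 0.32 (adjusted p = 0.000758, adjusted p = 0.498 with an estimated correlation, and 0.0671 with the preset one without replicate 1 of KO vehicle). Beside these, Kupffer cell markers had 7 higher of 15, including C1qb (1.04 ± 0.25), and the KO vehicle mice had the widest spread of that list (2.00 ± 0.75 SD, n = 3). The list had adjusted p = 0.00122, adjusted p = 0.439 with an estimated correlation, and 0.135 with the preset one without replicate 2 of KO vehicle. The neutrophil genes S100a8 (3.60 ± 0.75) and S100a9 (3.62 ± 0.82) rose, and the list of lymphocytes and neutrophils had 3 higher and 4 lower of 14 (median -0.52, mean 0.14) with no call. Red blood cell markers had 2 higher of 7, with Hbb-b2 at 2.80 ± 0.41 (adjusted p = 0.00991, adjusted p = 0.436 with an estimated correlation, and 0.0810 with the preset one without replicate 1 of KO vehicle).

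Among lists without a call, 5 of 18 circadian genes were lower, including Nr1d2 (-1.91 ± 0.24, but -0.35 with adjusted p = 0.103 at a second probe) and Hlf (-1.07 ± 0.14). Xenobiotic metabolism had 11 lower and 4 higher of 30, with Sult1e1 (4.75 ± 0.57), Cyp2b10 (5.11 ± 0.89) and Cyp2c37 (-1.77 ± 0.33, but -0.08 with adjusted p = 0.912 at a second probe), and its median (-0.29) and mean (0.01) differed in sign. Apolipoproteins (median -0.10, mean 0.07) and male-biased genes (median -0.33, mean 0.13) did so as well. Hepatocyte markers had 4 higher of 15 beside a median of -0.10. Some genes were not well above background in 1 genotype at their brightest probe. Dct (at least 126.3-fold) and Trim12a (at least 69.8-fold) were lower, and Tmc5 (at least 71.3-fold), Wdr72 (at least 12.5-fold) and Wif1 (at least 10.6-fold) higher. Under a slide block 4846 genes were called, and on slide 1, with 1 mouse of each group, 96.9% of called genes moved the same way. With the replicate number as a block 5135 were called, and the calls of Adgre1 (adjusted p = 0.0626) and Ltf (0.0578) were lost. Without replicate 2 of KO vehicle Adgre1 had an adjusted p of 0.853, and without replicate 1 Ltf had 0.140.

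Tested directly, the knockout effect differed between KO and LKO for 1369 genes, 563 with a higher value in KO and 806 lower. KO and LKO mice are separate lines, each set against its own controls. Other differences between the lines cannot be told apart from the extent of Ppara loss. Trim12a and Dct, above background on 0 of 3 KO vehicle arrays, and Camk2b, on 1 of 3, were among the lower genes, and Wdr72 and Tmc5, above background on all 3 KO arrays and on 0 and 1 of 4 LKO arrays, among the higher ones. Acute phase genes had 5 higher of 27, with Lcn2 (4.57 ± 1.21) and Serpina3n (1.75 ± 0.34) (adjusted p = 1.49e-05). Cholesterol synthesis had 5 higher and 1 lower of 25, with Dhcr7 at 1.23 ± 0.27 (0.00482), amino acid catabolism 3 higher and 1 lower of 30, with Aass at 1.26 ± 0.28 (0.00482), fatty acid synthesis 5 lower of 24, with Dgat2 at -0.80 ± 0.18 (0.0148), and circadian genes 3 lower of 18, with Nr1d2 at -1.84 ± 0.33 (0.0174), though a second probe of Nr1d2 gave -0.27 (adjusted p = 0.530). With an estimated correlation all 5 lost the call (adjusted p = 0.798 for the first 4 and 0.663 for circadian genes). Without replicate 1 of KO vehicle the cholesterol (0.214) and circadian (0.0801) calls were lost and the gene count was 2171, and without replicate 3 the amino acid (0.0740) and fatty acid (0.144) calls. A slide block gave 1609 genes and the replicate number as a block 1560, where Hal lost its call (adjusted p = 0.0556). Hal also had 0.188 without replicate 3 of KO vehicle, and its second probe gave -0.10 (adjusted p = 0.874).

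The knockout effects in LKO and KO, from separate mice, shared 476 lowered genes (116.4 expected, exact p = 2.82e-219) and 128 raised ones (39.2 expected, exact p = 1.18e-37). They held 22 and 10 genes of opposite direction, where 52.8 and 86.4 were expected, and correlated across genes at r = 0.476 (rho = 0.378). Drug and knockout were compared across lines so that no mouse was shared. Of genes raised by fenofibrate in WT, 433 were lower in LKO (67.8 expected, exact p = 4.05e-278), and of those lowered 117 were higher (34 expected, exact p = 5.23e-36), with r = -0.448 across genes. Of genes raised in LWT, 570 were lower in KO (296.5 expected, exact p = 6.65e-66), 205 were higher (220.0 expected), and of those lowered 232 were higher (156.0 expected, exact p = 7.57e-11), with r = -0.109. Genes are not independent replicates in these tests.

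The control lines themselves differed in vehicle mice (WT against LWT, 4 and 4) for 76 genes higher and 66 lower in WT. Bik (2.12 ± 0.23), Cdpf1 (1.77 ± 0.16, adjusted p = 1.21e-07), Tomm22 (1.75 ± 0.26) and Csad (1.18 ± 0.19), the gene of a taurine-forming enzyme, were higher in WT. Abcd2 (at least 2.43-fold) was higher too, and Jrk (at least 2.36-fold), Tspyl5 (at least 1.67-fold) and Cidec (-2.67 ± 0.61, adjusted p = 0.0241 but 0.147 without replicate 1 of WT vehicle) were lower. Cpt1a (-0.39 ± 0.08, adjusted p = 0.0108, but 0.0710 without replicate 1 of WT vehicle, and -0.41 with adjusted p = 0.127 at a second probe) was lower as well. Plin2 (-0.97 ± 0.26), Fgf21 (-2.10 ± 0.72), Cyp4a10 (-1.51 ± 0.67), Cyp4a14 (-1.87 ± 1.02), Ehhadh (-0.66 ± 0.30), Pdk4 (-0.89 ± 0.50), Vnn1 (-0.33 ± 0.40), Cd36 (0.09 ± 0.19) and Ppara (0.00 ± 0.16) were not called. The count was 57 without replicate 3 of LWT vehicle, and 82 and 79 without replicates 1 and 2 of WT vehicle. With slide as a block it was 172, with 79 genes higher and 93 lower in WT. With the replicate number as a block it was 171, where Plin2 passed (adjusted p = 0.0382), and all called genes moved the same way within slides 3 and 4.

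Peroxisomal oxidation (1 higher and 1 lower of 28, and 1 and 9 adjusted over the list alone), mitochondrial oxidation (2 lower of 22), other PPARA targets (1 lower of 19) and lipid uptake (3 lower of 27) were called lower in WT. So were amino acid catabolism (1 higher and 1 lower of 30, and 1 and 10 adjusted over the list alone) and cholesterol synthesis (1 lower of 25). Their adjusted p of 7.82e-09, 2.60e-09, 8.54e-06, 0.000744, 3.67e-08 and 0.00784 became adjusted p = 0.128, 0.128, 0.119, 0.128, 0.128 and 0.833 with an estimated correlation. The cholesterol call was lost without replicate 4 of WT vehicle (adjusted p = 0.157).

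Called genes gathered on chromosome 15, which carries Ppara. There 36 of 644 tested genes differed (odds ratio 8.45, exact adjusted p = 1.71e-17). Within 20 Mb of the Ppara probe (65632110 to 105632110) lay 19 of the 141 called genes with a position, 13.5% against 2.99% of tested genes (odds ratio 5.23, 3.02 to 8.62, exact p = 4.06e-08). Of the 19 genes 13 were higher and 6 lower in WT, at 0.01 to 16.4 Mb from the probe. They include Bik, Cdpf1, Tomm22, Csad and Jrk, and also Lgals1 (1.45 ± 0.23), Poldip3 (-0.73 ± 0.08) and Srebf2, a regulator of cholesterol synthesis (-0.84 ± 0.18, adjusted p = 0.0160 but 0.0869 without replicate 3 of LWT vehicle, and -0.45 with adjusted p = 0.158 at a second probe). Lgals1 and Poldip3 fall outside the naming rule and were chosen after their values were seen. The other 17 called genes of the chromosome lay outside the window, up to 81.7 Mb from the probe, among 174 tested, so that calls were denser there (9.77%) than among the 470 genes of the window (4.04%, odds ratio 0.390, 0.187 to 0.820, exact p = 0.0106). In LKO against LWT the odds ratio for the window was 0.895, in KO against WT 1.25 and for KO minus LKO 1.54 (exact adjusted p = 0.0174). For KO minus LKO calls were also denser on chromosomes 9 (odds ratio 1.52, exact adjusted p = 0.00462) and 7 (1.42, exact adjusted p = 0.00507). They were sparser on chromosomes 2 and X (exact adjusted p = 0.00462 and 0.00645). Chromosome 15 as a whole did not pass there (1.24, exact adjusted p = 0.484). Uneven calls for KO minus LKO were therefore not particular to the window. At most of the 19 genes of the window KO lay on the same side of WT as LWT, though KO and LWT were not compared directly. Of the 19, 18 were called in KO against WT, all with the opposite sign, but the shared WT vehicle mice favor opposite signs. In the fenofibrate mice, which are other animals, 17 were called, 16 with the opposite sign. There KO against WT called 6856 of all 15799 genes.

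**Figure D5:**
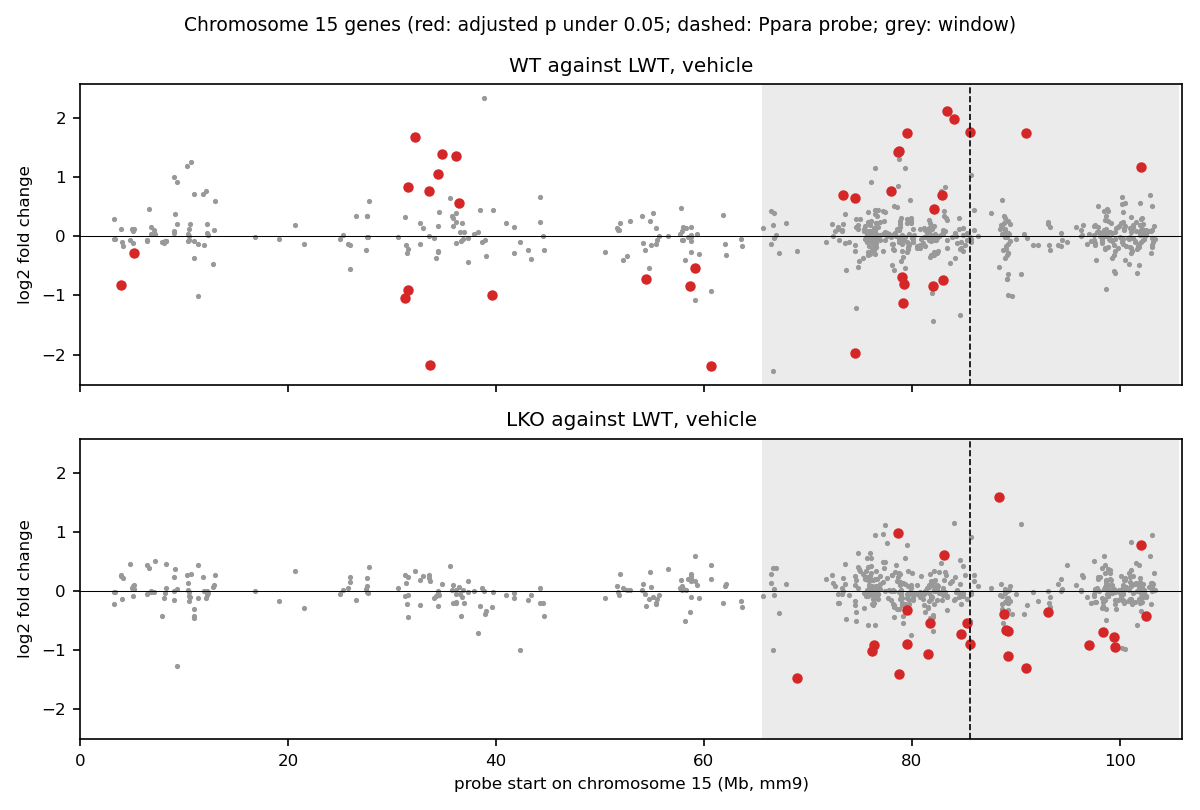
Log2 difference of each gene along chromosome 15 (position in Mb, mm9), WT against LWT in the upper panel and LKO against LWT in the lower one, called genes colored and the 20 Mb window around the Ppara probe shaded. Between WT and LWT 19 genes were called in the window and 17 elsewhere on the chromosome.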

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

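The tests weighed here were written before their results were seen, with these exceptions. Chosen after were the test of the KO arrays of slide 1 on genes lower in LKO mice, the comparison of the Ppara window with the rest of chromosome 15, the signs in KO against WT, the rule for a median not below 0 in the second pattern, and for KO minus LKO both the first scheme of splits below and the one that keeps pairs. The rules that leave splits undecided were also set after their results were seen. They cover a count of 0, paired vehicle mice and schemes that disagree.

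Of 147 groups of levels tested for a mouse far from the others, 10 held one, and chance marks about 1 in 20 groups, or 7.3 here. Fgf21 read -4.63 in replicate 3 of KO fenofibrate (others -6.61 to -6.24) and -3.31 in replicate 2 of LKO vehicle (others -6.92 to -6.47), levels near background. Cd36 read -0.64 in replicate 3 of LKO fenofibrate (others -0.24 to -0.11) and -0.49 in replicate 4 of WT vehicle (others 0.05 to 0.11).

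Among the marker lists, Kupffer cells averaged 2.06 in replicate 1 of WT fenofibrate (others 1.35 to 1.45). Lymphocytes and neutrophils averaged -0.79 in replicate 1 of LKO fenofibrate (others -1.27 to -1.21). Stellate cells averaged 0.49 in replicate 5 of LWT fenofibrate (others -0.30 to -0.17), and cholangiocytes -1.16 in replicate 2 of WT fenofibrate (others -0.73 to -0.68). In replicate 5 of KO fenofibrate adipocyte markers averaged 0.63 (others -0.90 to -0.64) and hepatocyte markers 8.09 (others 8.21 to 8.25).

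The effects of groups differed by a test of the difference itself in 3 cases. The fenofibrate response differed for 1083 genes between LWT and LKO and for 1785 between WT and KO, and the knockout effect differed for 1369 genes between KO and LKO. In the last case other differences between the lines cannot be told apart from the extent of Ppara loss.

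Other splits of the same mice tested whether chance could give such counts. Chance can be excluded at 5% where few splits reached the real count, the real split included. This was 1 of 35 splits for fenofibrate in WT (3397 genes, highest other 270) and 1 of 100 in LWT (2890, highest other 1792). For LWT minus LKO (1083, highest other 644) and WT minus KO (1785, highest other 117) it was also 1 of 100. The splits of these differences shuffled treatment within each line, which removes the response of the control line too. They exclude chance only for no response in either line, and cannot decide whether the responses of the lines are equal. The split with 1792 genes moved replicate 5 of LWT fenofibrate to the vehicle side.

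For KO minus LKO 4 of 100 splits gave as many genes (1369, highest other 3965), under shuffled genotypes within each pair of lines. An earlier scheme, which shuffled treatment within each line, gave 13 of 100 (highest other 2528), and exchanging genotypes only between same-numbered mice gave 14 of 100 (highest other 3486), so whether chance is excluded depends on the scheme. Shuffled genotypes can keep most of the contrast of KO and WT (4825 genes on its own) while mixing LKO and LWT. Counts as high as 3965 can therefore come from the genotype effect, and no scheme here tests whether the knockout effects are equal. For fenofibrate in KO 30 of 56 splits gave as many genes (3, highest other 1191), and chance cannot be excluded. The split with 1191 genes set replicate 1 of KO vehicle and replicate 1 of KO fenofibrate, both on slide 1, with replicate 2 of KO fenofibrate against the rest, which points to a structure of the samples. With slide as a block the real split gave 24 genes. Every split reaches a count of 0, so the splits say nothing for fenofibrate in LKO (100 of 100, 0 genes by limma with 904 at an unadjusted p under 0.05, highest other 3), LKO minus KO (100 of 100, 0 with 1460 unadjusted, highest other 152) or WT minus LWT (100 of 100, 0 with 696 unadjusted, highest other 12).

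Replicate numbers were taken to pair the vehicle mice, though many same-numbered mice also shared a slide. On that reading 7 other splits parted all pairs, too few for a share under 5%. They gave at most 0 genes for LKO against LWT (965 in the real split), 1908 for KO against WT (4825) and 2 for WT against LWT (142). The splits that parted fewer pairs gave at most 1, 3259 and 14. Ignoring the pairs, the real split alone reached its count in all 3 comparisons (1 of 35 each), a share under 5%, the bound of the rule written before. The split with 3259 genes moved replicate 1 of WT vehicle.

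The first pattern weighed was the gathering on chromosome 15 of genes that differed between WT and LWT vehicle mice, 19 within 20 Mb of Ppara and 17 further away, up to 81.7 Mb, where calls were denser (9.77% against 4.04%). The window test in the fenofibrate mice of these lines, which are other animals, gave an odds ratio of 9.85 (19 of 84 called genes, exact adjusted p = 6.14e-11), and there too calls were denser in the rest of the chromosome (11.5% against 4.04%). With slide as a block the odds ratio was 4.98 in vehicle mice and 4.94 in fenofibrate mice (18 of 140 called genes), which argues against slides as the whole cause. A segment of another strain kept around a targeted allele is a candidate explanation for the window, where LKO against LWT, which would share it, gave 0.895 and KO against WT in the separate fenofibrate mice called 17 of the 19 genes, 16 the opposite way, while for the 17 distant genes (8 called there, 5 the opposite way and 3 the same way) it stays open whether a segment would reach them. Sequence differences under single probes stay open, since second probes existed for 3 genes, and these changed the same way in 100% of cases.

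The second pattern was expected for replicate 1 of WT vehicle, the WT array on slide 1, and its presence depended on the reference. The 1691 genes induced in LWT had a median of 0.046 against the other WT vehicle mice, which is not below 0 but lies below all 1000 matched random sets (0.05 to 0.092) and below all genes of that array (0.071), and Cyp4a14 (2.39, others 6.55 to 8.09), Pdk4 (0.06, others 2.44 to 3.55) and Ehhadh (below the others, 5.41 to 6.89) were low there. Array quality and slide 1 (ratio 2.62) stay open for the induced genes, since the whole array lay above the others and the tests were written for a median below 0. The 290 genes lower in LKO and not induced were lower there (median -0.12), at percentile 0 of matched sets (lowest 0.005), so a difference in PPARA activity between mice may explain those genes. On them the KO arrays of slide 1 had medians of 0.033 (vehicle) and 0.072 (fenofibrate), with a mean of 0.053. All genes of these arrays had medians of 0.076 and 0.027. Relative to all genes the vehicle array lay lower and the fenofibrate array higher. They showed no common fall, which argues against a shared shift of slide 1, though on few arrays.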

How the results depend on the processing

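Leaving out the 3 arrays of slide 1 was chosen after seeing the data, and every alternative fixed before that was run. Where no cause is given below, the cause was not tested.

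Most results kept their direction and their side of the threshold. Over all alternatives, 27477 of 28920 values of named genes did so (95%), 1340 lost their call, 36 gained one and 67 changed sign. Of 581 named results 372 held under every alternative that could be run on them, 182 lost their call under at least 1, and 17 changed sign under at least 1. Of list calls 4984 of 5358 held (93%), 373 were lost and 1 changed direction. Counts of genes up or down stayed within 1.5 times in 1101 of 1224 cases (90%). Most of these values came from leaving out 1 array, often an array outside the comparison, so the pooled shares rest mainly on small changes. Of these fits 18937 of 19754 gene values and 3720 of 3876 list calls held. List calls held less often elsewhere, such as 88 of 114 with the authors' values and 29 of 114 with an estimated correlation. The authors' values gave 572 of the 581 named results, and the filter on probes above background on all arrays 460. The median of all genes moved most with the scaling in KO against WT, from -0.05 on the log2 scale to 0.006 with the authors' values.

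Every value that changed sign belonged to a change without a call, apart from 1 list. For fenofibrate in KO, array weights gave -0.126 for Cyp4a14, -0.053 for Pdk4 and -0.302 for Vnn1. The authors' values gave Cd36 -0.074, Cyp4a14 -0.609, Ehhadh -0.078, Pdk4 -0.275, Plin2 -0.05 and Vnn1 -0.375. Quantile-normalized median signals gave Vnn1 -0.06, and slide as a fixed block Pdk4 -0.074. Without the arrays of slide 1 Cyp4a10 was -0.549, Cyp4a14 -1.12, Pdk4 -0.361, Plin2 -0.031 and Vnn1 -0.565. KO vehicle then held 2 mice, and the cause was not tested beyond that.

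In the other comparisons the values that changed sign were small. For Ppara with fenofibrate in LWT the mean of a gene's probes gave 0.011, slide as a fixed block 0.068 and as a random block 0.026. In WT Ppara was -0.152 with the authors' values, 0 with slide as a fixed block and -0.029 without the arrays of slide 1. For WT against LWT Ppara was 0.172 with the authors' values, 0.004 after quantile normalization, 0.023 with slide as a fixed block and 0.054 without the arrays of slide 1. There too Cd36 was -0.001 with array weights, and Vnn1 0.171 with the authors' values. For KO against WT Cpt1a was 0.038 with the authors' values, 0.021 with quantile-normalized median signals and 0.032 after quantile normalization.

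With the replicate number as a block Pdk4 was -0.038 and Plin2 -0.003 for fenofibrate in KO, Ppara was 0.013 for fenofibrate in LWT, and 1 gene was called for fenofibrate in LKO. The knockouts kept their lower Ppara under this block (-0.905, adjusted p = 0.000293 in LKO, and -1.70, adjusted p = 3.78e-08 in KO), and 102 list calls stood against 114. The same-numbered mouse was the best match for 13 of 34 mice, and a mouse of the same slide for 16 of 34.

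Leaving out 1 array at a time gave these ranges for values that changed sign. For fenofibrate in KO they were -0.021 to 0.242 for Cd36, -0.477 to 1.701 for Cyp4a10, -1.23 to 1.527 for Cyp4a14, -0.401 to 0.436 for Pdk4 and -0.528 to 0.796 for Vnn1. All 5 changed sign without replicate 1 of KO vehicle, and the last 3 also without replicate 4 of KO fenofibrate. Plin2 (-0.07 to 0.229) did so without replicates 3 or 4 of KO fenofibrate or 2 of KO vehicle, and Fgf21 (-0.888 to 0.458) without replicate 2 of KO vehicle. The Kupffer list had an adjusted p from 7.3e-06 to 0.59, and without replicate 2 of KO vehicle its direction changed. For KO against WT Pdk4 ran from -1.069 to 0.206 (changed without replicate 1 of KO vehicle or 4 of WT vehicle) and Cpt1a from -0.149 to 0.023 (without replicate 2 of KO vehicle).

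For fenofibrate in LKO Cd36 ran from -0.159 to 0.021 (changed without replicate 3 of LKO fenofibrate or 2 of LKO vehicle). Cd36 in LKO against LWT ran from -0.143 to 0.083 (replicate 1 of LKO vehicle or 3 of LWT vehicle). Ppara lay near 0 throughout, at -0.119 to 0.075 in WT against LWT, -0.125 to 0.069 with fenofibrate in LWT and -0.029 to 0.109 in WT, and 5, 5 and 4 of the arrays changed its sign.

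Stricter thresholds lowered counts by construction. An adjusted p under 0.01 left 2017 genes for fenofibrate in WT, 1592 in LWT and 0 in KO, 551 for LWT minus LKO, 881 for WT minus KO, 569 for LKO against LWT, 3003 for KO against WT, 658 for KO minus LKO and 55 for WT against LWT. The overlaps then held 1126 genes for the WT and LWT responses, 326 for WT drug and LKO and 418 for LWT drug and KO. A change of at least 2-fold left 690, 543, 1, 394, 700, 321, 1189, 606 and 41 genes in the same order, and overlaps of 398, 144 and 132. Among these 690 genes 60.4% rose, against 47.5% of all called.

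Counts moved by more than 1.5 times under other choices as well. Array weights gave 14 genes for fenofibrate in LKO, 0 in KO, 2020 for LWT minus LKO, 3 for WT minus LWT, 1730 for LKO against LWT and 742 for WT against LWT. A fit of the compared groups alone, with fewer arrays to estimate the spread, gave 0 for fenofibrate in KO, 1044 for WT minus KO, 2090 for KO against WT and 55 for WT against LWT. The authors' values gave 2 for fenofibrate in LKO and 83 for WT against LWT. Their share of higher genes was 41.8% for LKO against LWT, against 31.2%. An estimated correlation left 29 list calls of 114.

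The counts near 0 moved by a few genes. For fenofibrate in LKO the intensity trend, quantile normalization and quantile-normalized median signals gave 2 genes each, only probes above background on all arrays 1, and leaving out slide 1 gave 4. For fenofibrate in KO the mean of a gene's probes and normexp gave 0, median signals 5, no detection filter 6, slide as a random block 8 and as a fixed block 24, and without slide 1 the count was 31. For WT minus LWT the trend, median signals, the filter on all arrays and the random slide block gave 1 each, normexp 2 and the fixed slide block 3. LKO minus KO gave 22 without slide 1.

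Leaving out 1 array gave 0 to 81 genes for fenofibrate in KO, 0 to 3 in LKO, 0 to 13 for LKO minus KO and 0 to 2 for WT minus LWT. It gave 1060 to 2171 for KO minus LKO and 57 to 211 for WT against LWT. The mice are named in the report beside these counts. For the other comparisons it gave 2578 to 3796 for fenofibrate in WT, 2241 to 3241 in LWT, 823 to 1313 for LWT minus LKO, 1422 to 2329 for WT minus KO, 685 to 1118 for LKO against LWT and 3936 to 5155 for KO against WT, all within 1.5 times. List calls numbered 107 to 118.

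Signal over background limits genes that are dark in a group, such as Fgf21 and Vnn1 in the knockouts, whose fitted changes depend on values near the floor. On simulated data a change of 1 on the log2 scale was recovered for 82% of genes for fenofibrate in LKO and 64% in KO, and for 56% for LKO minus KO. A change of 0.5 was recovered for 64%, 40% and 16%. Each share rests on 50 changed genes in 1 draw with independent noise. These draws gave 196, 175 and 162 called genes, against 0, 3 and 0 in the real data. More called genes make the adjusted threshold easier to pass, so the shares can overstate recovery in the real data.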

Other observations

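The test of the omega-oxidation list was chosen after its result was seen, and the comparisons of the fenofibrate-treated mice below were not among the planned ones.

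Mice that all received fenofibrate were also compared, in groups that mostly hold more mice than the vehicle groups, and differences between the counts were not tested. LKO against LWT gave 2873 genes higher and 2927 lower (965 in vehicle mice), and KO against WT 3251 higher and 3605 lower (4825 in vehicle mice). WT against LWT gave 51 higher and 34 lower (142 in vehicle mice). Circadian clock genes, which set daily rhythms, averaged 1.54 ± 0.15 (SD, n = 5) in LWT fenofibrate mice against 1.89 ± 0.09 (n = 4) with vehicle, and 1.97 ± 0.11 (n = 5) against 1.93 ± 0.08 (n = 4) in LKO. The male-biased list averaged 3.80 ± 0.38 against 4.51 ± 0.38 in LWT, and 4.64 ± 0.13 against 4.92 ± 0.07 in LKO. In KO it stood at 4.71 ± 0.14 with the drug and 4.36 ± 0.16 without.

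Levels of markers differed in spread as well as mean. The acute phase list averaged 6.68 ± 0.50 (n = 3) in KO vehicle mice and 5.31 ± 0.13 (n = 4) in WT. Red blood cell markers averaged 5.90 ± 0.29 in KO fenofibrate mice and 4.13 ± 0.30 in WT fenofibrate mice, and the 5 adipocyte markers -0.51 ± 0.64 and 0.89 ± 0.19. Pancreatic acinar markers averaged -1.76 ± 0.12 in KO vehicle mice and -1.98 ± 0.15 in WT. Lymphocyte and neutrophil markers averaged -0.92 ± 0.46 and -1.06 ± 0.15 in the same groups, and stellate cell markers 0.16 ± 0.11 and 0.01 ± 0.35. These levels were not tested further.

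The third pattern weighed was whether fenofibrate left a shared trace in mice without hepatic PPARA. The changes in LKO and KO correlated across genes at r = 0.055 (rho = -0.041), and 33.4% of 1000 relabelled data sets had a correlation as high, so chance may account for it. With slide as a block the correlation did not fall (0.07), but the relabelled values ran from -0.39 to 0.38, so a value this near 0 decides nothing about slides. Genes raised in both control lines rose in LKO by a median of 4.02% of the rise in LWT and in KO by -0.76% of that in WT, which argues against left-over PPARA signalling across those genes as a whole. It stays open for omega-oxidation genes, since that list leaned up in LKO (adjusted p = 0.00115, median 13.4% of that in LWT, with Cyp4a14 at 3.57 and Cyp4a10 at 1.81) and in KO (adjusted p = 0.0126, 22.7% of that in WT, but 0.496 without replicate 1 of KO vehicle, where Cyp4a10 was -0.477 and Cyp4a14 -1.23, and 0.0872 without replicate 1 of KO fenofibrate), without a call in either with an estimated correlation (adjusted p = 0.185 and 0.264).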
